A study of Mus musculus with 18 samples.

How the data were processed

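Gene expression was measured with Affymetrix MoGene-2_0 arrays in sorted thymic iNKT cells of C57BL/6 mice, 3 arrays for each of 6 groups (WT and Mst1KO at S1, S2 and S3), 18 in all. Thymocytes were enriched with CD8 microbeads before sorting, per the labels' protocols, which call the step positive selection. Since iNKT cells carry little CD8, whether the step kept or removed CD8-bearing cells is uncertain, and so is what a difference in Cd8b1 means. The deposited values are log2 expression per probe set, made by the authors with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA corrects background, brings the arrays to a common distribution and combines the probes of a probe set, so the values were already normalized between arrays. Which level of summary and which annotation the probe sets followed is not given in the sources used here. All values lay between 1.46 and 13.5, and the array medians between 4.81 and 4.93, near the signal of unexpressed probe sets, so changes among dim genes are compressed and measured less precisely.

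Of 41345 probe sets 23521 carried 1 gene symbol, 1814 several and 16010 none. Probe sets with 1 symbol were kept when they lay above their own array's median on at least 3 of the 18 arrays, which left 13702. The brightest probe set stood for each of the 513 genes with several, which gave 13034 genes. The gene names were those of the deposited table, and 193 of the single identifiers were absent from the RefSeq table for mouse assembly GRCm38.p6, which served only for names. Probe sets with no or several symbols were tested apart, and their counts are in the closing section.

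Differences were tested with limma 3.58.1 in R 4.3.3, as a linear model with a mean for each of the 6 groups and moderated t statistics. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Mst1KO was compared with WT at each stage, S2 with S1 and S3 with S2 within each genotype, and the difference of these stage changes between genotypes was tested as an interaction. For the average over stages, the S1, S2 and S3 values of the same genotype and replicate number were averaged first, giving 3 values against 3. Gene lists were fixed from general knowledge before the data were examined and tested with camera at a preset correlation of 0.01 between genes, then with an estimated correlation and with fry (statmod 1.5.0). Counts adjusted over the list alone apply the same adjustment to the members of a list only. Lists with fewer than 3 measured members were not tested.

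The rule for naming genes, written with the lists, takes Stk4, the 8 called genes with the largest increase and the 8 with the largest decrease whose arrays did not overlap in each comparison of genotypes at a stage and of WT stages, up to 4 members of each list described with the lowest p, and the 8 genes with the lowest p for the average over stages and each interaction. Any other list member could be named with its values. The genes called at all 3 stages were named after their values were seen. The maturation score used genes called between S1 and S3 in WT and was compared at S2 by an exact permutation test. The slope was fitted by total least squares to the S1 to S3 changes of all genes.

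The tests were tried on simulated data drawn from each gene's stage means and fitted variance. For Mst1KO against WT at S3, 37.3% of genes with an added log2 change of 0.5 were recovered, 92.5% of those with 1 and 98.5% of those with 2, and 5% of calls were unchanged genes. At S1 and S2, where no simulated gene was changed, limma called 0 genes each, and with none changed at S3, 2.5% of random lists had an unadjusted camera p under 0.05. Genes were simulated independently of each other, so this share does not test camera on lists whose members vary together.

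Alternatives tried were no filter and a stricter one at the 75th percentile, repeated quantile normalization, median centring, a variance trend with a robust fit, array weights, the mean of a gene's probe sets, an added 1.5-fold threshold, fits on only the groups compared, replicate number as a block, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.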

Results

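Gene expression was measured on 18 microarrays in invariant natural killer T (iNKT) cells from the mouse thymus, T cells that carry a semi-invariant receptor for lipids presented by CD1d. Cells came from wild-type (WT) C57BL/6 mice and from mice in which Cd4-driven Cre recombinase deletes Stk4, the gene for the Hippo pathway kinase MST1, in T cells (Mst1KO). Each genotype was sorted into 3 developmental stages, all binding the CD1d tetramer and lacking CD24: S1 (CD44 and NK1.1 negative), S2 (CD44 positive, NK1.1 negative) and S3 (CD44 and NK1.1 positive). Every combination of genotype and stage had 3 arrays, and this number limits the precision of every value. The series design gives 3 mice per genotype, but the labels do not say whether a replicate number marks a mouse, so p-values measure the spread between these samples, which may be partly technical. Values are log2 expression, differences are given as log2 difference ± SE with n = 3 per group unless another n is stated, and group levels as mean ± SD (n = 3). Of 13034 genes tested, those with an adjusted p under 0.05 are called changed.

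The arrays of a group resembled each other (r across probe sets 0.976 to 0.986), and no array duplicated another. The main axis of variation, with 56.1% of the variance, ordered the samples by stage. The next, with 9.76%, separated the genotypes most at S2 and S3, and also set S2 apart from S1 and S3 within each genotype. On the main axis the genotypes did not overlap at S1 or at S3. Stk4, the targeted gene, was lower in Mst1KO at each stage without passing the test: -0.29 ± 0.11 at S1, -0.35 ± 0.11 at S2 and -0.39 ± 0.11 at S3, with adjusted p = 0.34, 0.173 and 0.0767. Its level was 7.90 ± 0.20, 7.83 ± 0.09 and 8.04 ± 0.21 in WT and 7.61 ± 0.05, 7.48 ± 0.07 and 7.66 ± 0.09 in Mst1KO at S1, S2 and S3. Within each stage every WT array lay above every Mst1KO array, the lowest WT and highest Mst1KO values being 7.70 and 7.67 at S1, 7.73 and 7.54 at S2, and 7.80 and 7.74 at S3. A probe set of this array covers a whole transcript, including parts that a conditional deletion can leave in place, so this modest difference is a weak check of the labels.

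**Figure D1:**
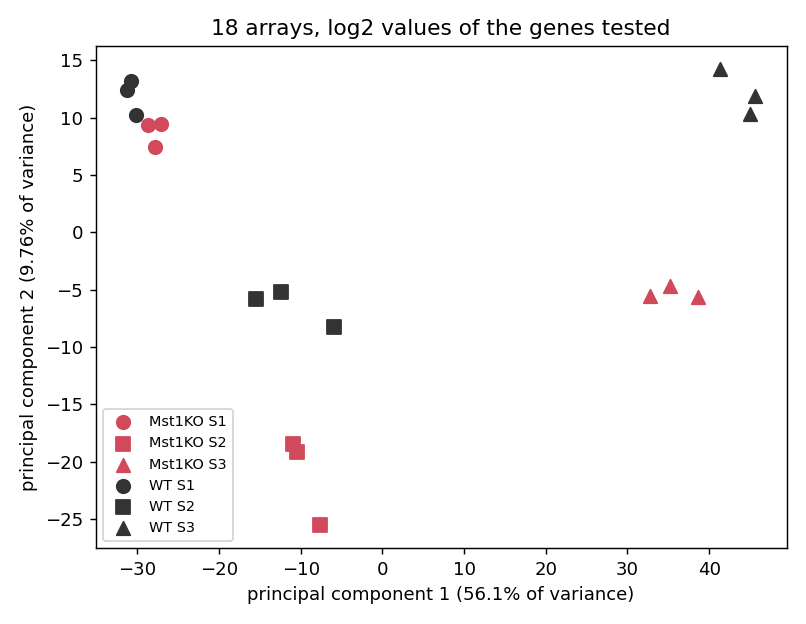
Principal components 1 and 2 of the 18 arrays (axes in component units, percent of variance in brackets), with 1 point per array, shape for stage and colour for genotype. Stages separate along component 1 (56.1%), where the genotypes also do not overlap at S1 and S3. Along component 2 (9.76%) the genotypes lie furthest apart at S2 and S3, and S2 lies apart from S1 and S3 within each genotype.

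The WT stages are the sorted populations against which the knockout was set. Each is a bulk sort, so a change between stages may be a different mix of cells or a change per cell. The gates on CD44 and NK1.1 can set part of this mix, and the possibilities were not told apart. From S1 to S2 in WT, RNA of both the NKT1 and the NKT17 effector programs rose. The largest increases were Il23r, the IL-23 receptor (4.66 ± 0.56), the chemokine gene Xcl1 (3.24 ± 0.34), the IL-1 receptor gene Il1r1 (3.23 ± 0.29), granzyme B (Gzmb, 3.04 ± 0.48) and Stat4, which carries the IL-12 signal (2.69 ± 0.29). Serpinb1a (2.48 ± 0.26), Tmem176b (2.47 ± 0.20) and the IL-12 receptor chain Il12rb2 (2.46 ± 0.33) followed. Decreases were led by the peptide transporter Slc15a1 (-2.83 ± 0.25), with Ptpn14 at -1.58 ± 0.25, Akr1c18 at -1.53 ± 0.36, Lztfl1 at -1.50 ± 0.27, Ceacam1 at -1.47 ± 0.24, the chemokine receptor Ccr9 at -1.42 ± 0.16, heparanase (Hpse) at -1.40 ± 0.26 and the urokinase receptor Plaur at -1.36 ± 0.20.

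Of 18 measured NKT1 genes 15 rose and 3 were not called, or 17 higher when adjusted over the list alone (camera adjusted p = 2.79e-28). They included Ly6c2 (2.01 ± 0.16), Klrb1c, which encodes NK1.1 (2.19 ± 0.23), and the NKT1 regulator Tbx21 (1.21 ± 0.15). Of 17 NKT17 genes 11 rose and 6 were not called, or 13 higher when adjusted over the list alone (adjusted p = 1.03e-21), including Ccr6 (2.18 ± 0.26), Cd44 (1.97 ± 0.14), which also defines the S2 gate, and Il17re (1.90 ± 0.23). Immediate early genes rose as a list, 10 of 23 higher and 14 when adjusted over the list alone (adjusted p = 3.61e-15), among them Junb (0.97 ± 0.10), Fos (1.20 ± 0.21) and Tnfaip3 (0.82 ± 0.12). These 3 lists kept their calls with adjusted p = 0.00614 for each with an estimated correlation. The NK receptor list had 5 of 12 members higher, 6 when adjusted over the list alone, among them Klrd1 at 2.20 ± 0.49 and Klrk1 at 1.19 ± 0.26 (adjusted p = 1.73e-07; adjusted p = 0.0466 with an estimated correlation). Klrk1 lost its call in 4 and Klrd1 in 3 of 6 fits without an array. Both genes are also in the NKT1 list. Of the NK receptor genes 5 of 12, and of the NKT1 genes 8 of 18, are in another list, so these list calls are not independent. The TGF-beta and residency list had 6 of 13 higher, with Rgs1 at 2.16 ± 0.25 and Itgae, the residency integrin CD103, at 0.92 ± 0.15; 6 were higher when adjusted over the list alone (adjusted p = 1.73e-07; adjusted p = 0.0143 with an estimated correlation).

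DNA replication genes fell, 5 of 24 lower and 19 not called, 18 lower when adjusted over the list alone (adjusted p = 3.26e-12, but adjusted p = 0.106 with an estimated correlation). Examples were Tyms (-0.79 ± 0.15), Mcm7 (-0.52 ± 0.12) and Cdc6 (-0.79 ± 0.19), of which Mcm7 and Cdc6 lost their calls in 4 of 6 fits without an array. Markers of conventional mature T cells, another cell type of the thymus, were lower at S2 in the same comparison: 4 of 10 fell, 6 when adjusted over the list alone, with Igfbp4 at -1.30 ± 0.15 and Lef1 at -0.75 ± 0.12 (adjusted p = 1.88e-06, adjusted p = 0.0603 with an estimated correlation). B cell markers were higher as a list although 0 of 5 passed singly, over all genes or adjusted over the list alone (adjusted p = 0.0133, adjusted p = 0.109 with an estimated correlation). Of 6 NK and innate lymphoid markers 2 were higher either way (adjusted p = 0.00934, adjusted p = 0.052 with an estimated correlation).

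In all 501 genes changed, 352 higher and 149 lower, and in 493 of the 501 the 3 arrays of each stage did not overlap. Non-overlap held for 19.9% of all genes, where chance gives 10%. A fit on only these groups called 195 genes. The fit without WT S1 replicate 1 called 309, without WT S1 replicate 2 called 321 and without WT S2 replicate 1 called 295.

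From S2 to S3, the sorted WT populations differed by a more NK-like profile and lower RNA of cell cycle and NKT2 genes. NK receptor genes dominated the increases, with Klra5 at 6.07 ± 0.60, Klre1 at 5.94 ± 0.24, Klra9 at 5.13 ± 0.31, Klrk1 at 4.56 ± 0.26, Klrc3 at 4.47 ± 0.32 and Klrc1 at 4.30 ± 0.45. The collagen-binding integrin Itga1 (4.28 ± 0.43) and Gzmb (4.19 ± 0.48) were also among the 8 largest. The Klra genes, the Ly49 family, are near-identical copies of each other, so which member a probe set reads is uncertain. The largest decreases were the microRNA gene Mir181b-1 (-4.47 ± 0.57), Emb (-4.13 ± 0.24), the prohormone convertase Pcsk1 (-4.04 ± 0.35), Il23r (-4.01 ± 0.56), the IL-25 receptor gene Il17rb (-3.95 ± 0.18), Il6ra (-3.51 ± 0.17), Smtn (-3.40 ± 0.15) and Depdc1a (-3.40 ± 0.41).

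All 18 NKT1 genes rose (camera adjusted p = 1.31e-21), with Ccl5 at 3.56 ± 0.24, Ifng at 2.65 ± 0.20 and Klrb1c at 3.24 ± 0.23, the last part of the S3 gate, and all 12 NK receptor genes rose (adjusted p = 3.44e-16). Of 11 cytotoxic granule genes 6 rose, 8 when adjusted over the list alone, with perforin (Prf1) at 3.28 ± 0.23 and Gzma at 3.69 ± 0.44 (adjusted p = 1.83e-05). All 13 NKT2 genes fell, among them Ccr4 (-2.87 ± 0.21) and Zbtb16, the gene for the iNKT regulator PLZF (-1.32 ± 0.12; adjusted p = 1.84e-15). All 25 mitosis genes fell, led by Cdk1 (-3.13 ± 0.20) and Top2a (-3.04 ± 0.21; adjusted p = 3.39e-31), as did 23 of 24 DNA replication genes, with Uhrf1 at -2.15 ± 0.17 (adjusted p = 2.07e-19). The full counts of the NKT1, NK receptor, NKT2, mitosis and replication lists were the same when adjusted over the list alone. With an estimated correlation these 6 lists kept their calls, with adjusted p = 0.0126 for NKT1, 0.0074 for NK receptors, 0.0487 for cytotoxic genes, 0.0074 for NKT2, 0.0271 for mitosis and 0.0332 for replication.

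Of 17 NKT17 genes 12 fell, Cd44 rose (0.55 ± 0.14) and 4 were not called, with the same counts when adjusted over the list alone. Nrp1 at -2.08 ± 0.14, Il1r1 at -2.85 ± 0.29 and Serpinb1a at -2.49 ± 0.26 were lower (adjusted p = 3.55e-07; adjusted p = 0.0515 with an estimated correlation). Gamma-delta T cell markers fell with them, 2 of 3 called and 3 lower when adjusted over the list alone, Cd163l1 at -1.51 ± 0.12 and Blk, which is in both lists, at -2.83 ± 0.30 (adjusted p = 0.00107, adjusted p = 0.0487 with an estimated correlation). Of 10 conventional T cell markers 6 fell, 6 lower and 1 higher when adjusted over the list alone, with Igfbp4 at -2.66 ± 0.15 (adjusted p = 3.89e-05, adjusted p = 0.0671 with an estimated correlation). In the quiescence and egress list 6 of 17 rose and 4 fell, 8 and 4 when adjusted over the list alone, and the list was not called (adjusted p = 0.0878). S1pr1, the receptor that guides T cells out of the thymus (-2.49 ± 0.16), and Ccr7 (-2.35 ± 0.20) fell, while Tsc22d3 (0.89 ± 0.10) and Btg2 (0.89 ± 0.10) rose. Markers of NK cells and innate lymphoid cells moved with the NKT1 list: 4 of 6 rose and 2 fell, with the same counts when adjusted over the list alone, Fcer1g at 3.18 ± 0.16 and Tyrobp at 2.01 ± 0.19 (adjusted p = 0.0131, adjusted p = 0.0487 with an estimated correlation). Macrophage and dendritic cell markers did so too, with 5 of 13 higher, 7 when adjusted over the list alone, and 1 lower either way, C1qb at 1.05 ± 0.23 and Lyz2 at 1.38 ± 0.34 (adjusted p = 0.00931, adjusted p = 0.15 with an estimated correlation). Fcer1g is in both marker lists. Of 5 B cell markers 2 were higher either way (adjusted p = 0.0295, adjusted p = 0.128 with an estimated correlation).

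In all 3073 genes changed, 1356 higher and 1717 lower, and 2932 of them did not overlap between stages (34.9% of all genes, chance 10%). With a threshold of at least 1.5-fold added, 1560 remained, and a fit on only these groups called 2037.

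The sorted stages of Mst1KO differed from each other in much the same way. From S1 to S2, 13 of 17 NKT17 genes rose, with Il1r1 at 5.28 ± 0.28, Serpinb1a at 4.26 ± 0.26 and Ccr6 at 3.78 ± 0.26 (camera adjusted p = 1.1e-25, adjusted p = 0.00572 with an estimated correlation). Of 18 NKT1 genes 9 rose, 14 when adjusted over the list alone, including Cxcr3 at 1.64 ± 0.16 and Tbx21 at 1.00 ± 0.15, while Stat4 (0.81 ± 0.29) and Il12rb2 (0.37 ± 0.33) did not pass (adjusted p = 6.63e-14, adjusted p = 0.0369 with an estimated correlation). The S1 to S2 change of the NKT17 list was higher in Mst1KO than in WT by a median of 0.88 (adjusted p = 1.66e-09, adjusted p = 0.23 with an estimated correlation). That of the NKT1 list was lower, by a median of -0.35 (adjusted p = 0.000309, adjusted p = 0.605 with an estimated correlation). From S2 to S3, all 18 NKT1 genes rose in Mst1KO (adjusted p = 3.39e-30, 0.00464 with an estimated correlation), all 25 mitosis genes fell (adjusted p = 7.09e-27, 0.0311 with an estimated correlation), and 12 of 13 NKT2 genes fell while Izumo1r rose (0.45 ± 0.14; adjusted p = 3.05e-12, 0.00839 with an estimated correlation). NK receptor genes rose in 10 of 12 cases, with Klra5 at 7.32 ± 0.60 and Klre1 at 6.33 ± 0.24, whereas Klrb1f (0.38 ± 0.31) and Ncr1 (0.08 ± 0.33) were not called (adjusted p = 2.57e-19, 0.00464 with an estimated correlation). The counts of the NKT17 list from S1 to S2, and of the NKT1, mitosis, NKT2 and NK receptor lists from S2 to S3, were the same when adjusted over the list alone.

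Markers of other cells moved with these changes in Mst1KO. From S1 to S2 the gamma-delta T cell list was higher, 1 of 3 called either way, Blk (3.46 ± 0.30), with adjusted p = 0.0436 and adjusted p = 0.213 with an estimated correlation. Of 13 macrophage and dendritic cell markers 6 were higher and 1 lower, 7 and 1 when adjusted over the list alone (adjusted p = 0.00252, adjusted p = 0.129 with an estimated correlation). NK and innate lymphoid markers rose in 3 of 6 cases either way (adjusted p = 0.00173, adjusted p = 0.0369 with an estimated correlation), and 6 of 10 conventional T cell markers fell, 7 when adjusted over the list alone (adjusted p = 3.62e-09, adjusted p = 0.0369 with an estimated correlation). From S2 to S3 the NK and innate lymphoid list had 3 of 6 higher and 1 lower either way (adjusted p = 0.00471, adjusted p = 0.0311 with an estimated correlation). The macrophage list had 6 of 13 higher and 1 lower either way (adjusted p = 0.00694, adjusted p = 0.14 with an estimated correlation). Of 17 NKT17 genes 10 fell and 1 rose, 12 and 1 when adjusted over the list alone (adjusted p = 1.05e-06, adjusted p = 0.0686 with an estimated correlation). The gamma-delta list had 2 of 3 lower either way (adjusted p = 0.0203, adjusted p = 0.14 with an estimated correlation). Of 10 conventional T cell markers 6 were lower, 7 lower and 1 higher when adjusted over the list alone (adjusted p = 1.35e-05, adjusted p = 0.0686 with an estimated correlation).

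In Mst1KO, 870 genes changed from S1 to S2 (492 higher, 378 lower) and 2240 from S2 to S3 (1044 higher, 1196 lower). With quantile normalization repeated, the latter split was 880 higher and 1563 lower. Of the genes higher from S1 to S2, 223 were shared between genotypes where independent lists would share 13.3, and of those lower 91 against 4.32. From S2 to S3, 698 higher genes were shared against 109 by chance and 849 lower against 158. No array and no genotype entered both sides of these overlaps. Without Mst1KO S2 replicate 1, 530 genes were called from S1 to S2.

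The comparison of Mst1KO with WT at each stage asks which genes differ between the genotypes. A difference need not come from loss of MST1 itself, and where the genes lie relative to Stk4 or to each other was not examined. At S1, the largest differences were losses of Laptm4b, a lysosomal membrane protein gene (-2.60 ± 0.21, 6.07-fold lower, adjusted p = 1.83e-05), and of the matrix protein gene Matn2 (-2.26 ± 0.21). Atp8a2, a phospholipid flippase (-0.93 ± 0.17), the RNA editing gene Adarb1 (-0.78 ± 0.13), Ttc39c (-0.70 ± 0.12), the insulin receptor substrate Irs1 (-0.66 ± 0.13), the cytokine gene Il4 (-0.64 ± 0.12) and Ddx43 (-0.61 ± 0.10) were lower too. Increases were led by Neurl3 (1.38 ± 0.20, 2.6-fold), the clock gene Nr1d1 (1.23 ± 0.20), the IL-4 receptor gene Il4ra (1.08 ± 0.18), Ly6c2 (1.05 ± 0.16), Qpct (1.05 ± 0.15), the Toll-like receptor Tlr1 (0.99 ± 0.12), the death receptor gene Tnfrsf25 (0.93 ± 0.18) and Wfikkn2 (0.87 ± 0.14). Among them Atp8a2, Il4 and Tnfrsf25 lost their calls in 6 of 6 fits without an array, Irs1 and Wfikkn2 in 5, and Adarb1, Ttc39c, Ddx43 and Il4ra in 4.

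Quiescence and egress genes were higher as a list in Mst1KO at S1, with 16 of 17 members positive and a median of 0.36 (camera adjusted p = 4.88e-11), and the call held, near the threshold, at adjusted p = 0.0496 with an estimated correlation. None of its members passed over all genes (0 of 17), and 12 were higher when adjusted over the list alone. Slfn2, known to keep T cells quiescent, was at 0.52 ± 0.11, Txnip at 0.63 ± 0.14, S1pr1 at 0.68 ± 0.16 and Klf2, a regulator of T cell trafficking, at 0.80 ± 0.21. Markers of conventional mature T cells moved with this list (median 0.41, adjusted p = 0.000661, adjusted p = 0.479 with an estimated correlation), with 0 of 10 called over all genes and 5 when adjusted over the list alone. Of the 7 markers outside the quiescence list 6 were positive, with Cd8b1 at 0.80 ± 0.30 and Actn1 at 0.55 ± 0.19. DNA replication genes were lower, 0 of 24 positive, median -0.16 (adjusted p = 0.000382, adjusted p = 0.774 with an estimated correlation), with Chaf1a at -0.37 ± 0.16 and Mcm6 at -0.20 ± 0.10. Mitosis genes were lower as well, median -0.17 (adjusted p = 0.00452, adjusted p = 0.774 with an estimated correlation), and 0 members of either list passed over all genes or adjusted over the list alone. In the adhesion and actin list 1 of 18 rose, the integrin gene Itga4 (0.83 ± 0.15), and 2 when adjusted over the list alone (adjusted p = 0.0193, adjusted p = 0.184 with an estimated correlation). Without single arrays the adhesion list lost its call in 3 of 6 fits, the mitosis list in 2 and the conventional T cell list in 1.

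In all 43 genes changed at S1, 34 higher and 9 lower, and the arrays of the genotypes did not overlap in any of the 43 (18.1% of all genes, chance 10%). Leaving out WT replicate 1, 2 or 3 gave 20, 14 and 23 genes. Leaving out Mst1KO replicate 1, 2 or 3 gave 9, 12 and 13. Of 17 named calls at S1, those of Laptm4b, Matn2, Tlr1 and Qpct held in every such fit and 13 were lost in at least 1. A fit on only the 6 S1 arrays called 5 genes, and other settings called 28 (no filter) to 128 (variance trend and robust fit).

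At S2, the genes that differed included 6 of 17 NKT17 genes, all higher in Mst1KO, and 3 of 18 NKT1 genes, all lower. Neither list kept its call with an estimated correlation (adjusted p = 0.197 and 0.337). Klrb1b (1.82 ± 0.24, 3.53-fold higher), the unnamed transcript A530021J07Rik (1.63 ± 0.26), Nr1d1 (1.57 ± 0.20), the chemokine receptor Ccr6 (1.51 ± 0.26), Lingo4 (1.49 ± 0.25), Mmp25 (1.39 ± 0.24), the proteoglycan Sdc1 that marks NKT17 cells (1.30 ± 0.23) and Serpinb1a (1.29 ± 0.26) rose most. Xcl1 (-2.18 ± 0.34, 4.53-fold lower), Akr1c18 (-1.98 ± 0.36), Il12rb2 (-1.97 ± 0.33), the macrophage growth factor gene Csf1 (-1.78 ± 0.20), Lgi2 (-1.54 ± 0.27), the inflammatory caspase Casp1 (-1.45 ± 0.25), Ifi204 (-1.43 ± 0.32) and Matn2 (-1.42 ± 0.21) fell most. Ifi204 lost its call in 4 of 6 fits without an array and Serpinb1a in 3.

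Of the NKT17 genes 11 were not called, or 11 were higher when adjusted over the list alone, and the list mean was 8.76 ± 0.19 in Mst1KO against 8.05 ± 0.25 in WT (camera adjusted p = 5.32e-10, adjusted p = 0.197 with an estimated correlation). Tmem176b (1.20 ± 0.20), the IL-17 receptor chain Il17re (1.22 ± 0.23) and Il1r1 (1.27 ± 0.28) were among them, while the lineage regulator Maf (0.01 ± 0.14) and Il17a (0.03 ± 0.20) were not. The NKT1 genes that fell were Xcl1, Il12rb2 and Ccl5 (-1.03 ± 0.24). Ccl5 lost its call in 5 of 6 fits without an array. The NKT1 mean of WT replicate 2 (7.44) lay within the Mst1KO range of 7.29 to 7.47. Adjusted over the list alone 5 were lower and 1 higher (adjusted p = 2.13e-06, adjusted p = 0.337 with an estimated correlation). Of 13 NKT2 genes 3 fell, Il4 (-1.11 ± 0.12), Il13 (-0.87 ± 0.18) and Izumo1r (-0.59 ± 0.14), 4 lower and 1 higher when adjusted over the list alone (adjusted p = 0.0119, adjusted p = 0.343 with an estimated correlation). Izumo1r lost its call in 5 of 6 fits without an array and Il13 in 3. The cytotoxic list was lower with 0 of 11 called either way, Gzmb at -1.47 ± 0.48 and Prf1 at -0.57 ± 0.23 (adjusted p = 0.00526, adjusted p = 0.337 with an estimated correlation). Its mean in WT replicate 2 (7.44) lay below the highest Mst1KO mean (7.46). The NKT2 and cytotoxic lists each lost their call in 1 of 6 fits without an array.

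DNA replication genes were lower in Mst1KO at S2, 0 of 24 positive and 0 called, 1 lower when adjusted over the list alone, with Pole at -0.56 ± 0.15 (adjusted p = 4.11e-08, adjusted p = 0.337 with an estimated correlation). Mitosis genes were lower, 0 of 25 called either way, with Hmmr at -0.59 ± 0.18 (adjusted p = 3.54e-06, adjusted p = 0.4 with an estimated correlation). The arrays overlapped in both lists. The mitosis mean of WT replicate 1 (8.14) lay below those of Mst1KO replicates 2 and 3 (8.17 and 8.15), and the replication mean of WT replicate 1 and Mst1KO replicate 3 was 8.19. The quiescence list was higher, 0 of 17 called and 4 higher when adjusted over the list alone, with the cell cycle inhibitor Cdkn1b at 0.50 ± 0.12 and Klf2 at 0.79 ± 0.21 (adjusted p = 0.000329, adjusted p = 0.337 with an estimated correlation). In the FOXO and antioxidant list Gpx1 (0.39 ± 0.08) and the glutathione synthesis gene Gclc (0.68 ± 0.15) rose, 2 of 15, and 4 when adjusted over the list alone (adjusted p = 0.0285, adjusted p = 0.337 with an estimated correlation). Gpx1 lost its call in 6 of 6 fits without an array and Gclc in 5. The FOXO and antioxidant list lost its own call in 3 of these 6. The co-stimulation list was lower, 0 of 12 called and 1 lower when adjusted over the list alone, with Pdcd1 at -0.51 ± 0.15 (adjusted p = 0.0119, adjusted p = 0.337 with an estimated correlation), with the lowest WT and the highest Mst1KO array both at 7.69. It lost its call in 2 of 6 fits without an array. Markers of other cells that rose here were Cd163l1 of gamma-delta T cells (0.64 ± 0.12) and Itgax of dendritic cells (0.93 ± 0.18), with their lists not called (adjusted p = 0.0715 and 0.0692). Cd163l1 lost its call in 2 and Itgax in 4 of 6 fits without an array.

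In all 152 genes changed at S2, 93 higher and 59 lower, none of them with overlapping arrays (non-overlap in 16.8% of all genes, chance 10%). Without WT replicate 2 the count was 112, with 56 higher and 56 lower. Without WT replicate 3 it was 72 (45 higher, 27 lower), and without Mst1KO replicate 1 it was 39 (20 higher, 19 lower). Of 32 named calls at S2 22 were lost in at least 1 such fit. A fit on only the 6 S2 arrays called 4 genes, array weights gave 97 and a variance trend with a robust fit gave 248.

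At S3, Mst1KO cells carried more RNA of 10 of 17 NKT17 genes (adjusted p = 0.055 for the list with an estimated correlation), of the integrin gene Itga4 (1.93 ± 0.15) and of the egress receptor gene S1pr1, and less of granzyme A, Ccl5 and interferon-induced transmembrane genes. Il23r (3.56 ± 0.56, 11.8-fold higher), Emb (2.68 ± 0.24), the cGMP phosphodiesterase Pde5a (2.65 ± 0.25), Serpinb1a (2.64 ± 0.26), the kinase gene Blk (2.39 ± 0.30), S1pr1 (2.32 ± 0.16), Tlr1 (2.21 ± 0.12, adjusted p = 4.15e-08) and Mmp25 (2.20 ± 0.24) rose most. Ifitm2 (-3.77 ± 0.37, 13.6-fold lower), Gzma (-3.44 ± 0.44), Atp8a2 (-2.45 ± 0.17), Ifitm1 (-2.21 ± 0.17), the sulfatase gene Sulf2 (-2.20 ± 0.22), Apol9b (-2.19 ± 0.23), the tight junction gene Tjp1 (-2.06 ± 0.33) and Ifitm3 (-2.02 ± 0.27) fell most. The Ifitm genes resemble each other in sequence, so how far their probe sets tell them apart is uncertain.

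Of 17 NKT17 genes 10 rose and 7 were not called, 14 higher when adjusted over the list alone. The list mean was 7.85 ± 0.07 in Mst1KO against 6.64 ± 0.29 in WT (camera adjusted p = 1.24e-14, adjusted p = 0.055 with an estimated correlation), with Ccr6 at 2.03 ± 0.26, Il1r1 at 2.14 ± 0.29 and Sdc1 at 1.65 ± 0.23. Gamma-delta T cell markers moved with it, 2 of 3 higher either way, Cd163l1 (1.03 ± 0.12) and Blk, which is in both lists (adjusted p = 0.000145, adjusted p = 0.0878 with an estimated correlation). In the NKT2 list, which was not called (adjusted p = 0.149), Il17rb (2.03 ± 0.18), Il6ra (0.99 ± 0.17) and Slamf6 (1.69 ± 0.36) rose while Il4 (-0.98 ± 0.12) fell, 6 higher and 3 lower of 13 when adjusted over the list alone. The NKT1 list was not called (adjusted p = 0.326), with Ccl5 lower (-1.93 ± 0.24), the same count of 1 lower of 18 when adjusted over the list alone, and Tbx21 (-0.06 ± 0.15) and Klrb1c (0.26 ± 0.23) not called. Of 11 cytotoxic genes Gzma and Prf1 (-0.89 ± 0.23) fell, 2 either way, with the list at adjusted p = 0.0613. Prf1 lost its call in 5 of 6 fits without an array.

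Mitosis genes were higher in Mst1KO at S3, 4 of 25 called, 18 when adjusted over the list alone, with Ube2c (0.80 ± 0.21), Cdk1 (0.74 ± 0.20), Aurka (0.72 ± 0.19) and Hmmr (0.68 ± 0.18; adjusted p = 1.36e-07, adjusted p = 0.529 with an estimated correlation). These 4 calls were each lost in 5 of 6 fits without an array, while the list kept its call in all 6. The list mean was 5.58, 5.64 and 6.34 in the WT arrays and 6.11, 6.41 and 6.53 in the Mst1KO arrays, so WT replicate 3 lay above Mst1KO replicate 1. DNA replication genes were higher, Gins1 (1.06 ± 0.22) rising as 1 of 24 either way (adjusted p = 0.00441, adjusted p = 0.589 with an estimated correlation). The replication list lost its call in 2 of 6 fits without an array. Here too WT replicate 3 (7.38) lay above Mst1KO replicate 1 (7.27). The interferon response list was lower with 0 of 17 called either way, Rtp4 at -0.40 ± 0.11 (adjusted p = 0.00145, adjusted p = 0.441 with an estimated correlation). In the TGF-beta and residency list Itgae fell (-0.75 ± 0.15), 1 of 13, with 3 lower and 1 higher when adjusted over the list alone (adjusted p = 0.0249, adjusted p = 0.441 with an estimated correlation). This list lost its call in 3 of 6 fits without an array. Single genes of lists that were not called changed as well. The apoptosis effector Bak1 rose (0.56 ± 0.10) and Bcl2l11, the gene for BIM, fell (-0.98 ± 0.19). Nr4a1 rose (0.63 ± 0.12) while Junb (-0.49 ± 0.10) and Fosl2 (-0.82 ± 0.17) fell, and the inhibitory receptor gene Tigit fell (-1.40 ± 0.35). The Hippo kinase gene Stk38 rose (0.55 ± 0.12). Among markers of other cells, C1qb (0.94 ± 0.23), Tyrobp (0.88 ± 0.19) and Themis (0.88 ± 0.19) rose and Cd22 fell (-1.22 ± 0.14). Without single arrays Tigit, C1qb and Themis lost their calls in 4 of 6 fits and Stk38 and Tyrobp in 3.

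In all 443 genes changed at S3, 306 higher and 137 lower, and 436 of them did not overlap between genotypes (23% of all genes, chance 10%). With quantile normalization repeated the split was 230 higher and 173 lower of 403. Without WT replicate 1 the count was 289, and without Mst1KO replicate 1, 2 or 3 it was 239, 255 and 200. Of 53 named calls at S3 21 were lost in at least 1 such fit. A fit on only the 6 S3 arrays called 184 genes.

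**Figure D2:**
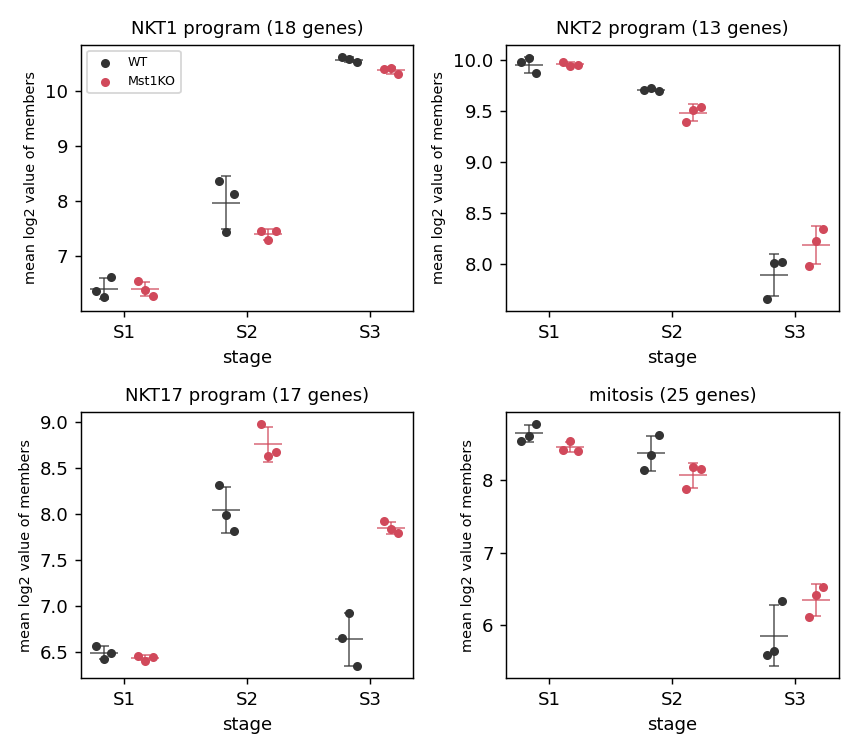
Mean log2 value of the measured members of the NKT1 (18 genes), NKT2 (13), NKT17 (17) and mitosis (25) lists on each array by stage, with points for arrays, bars for the group mean and SD (n = 3), WT in black and Mst1KO in red. The NKT17 mean at S3 was 7.85 ± 0.07 in Mst1KO and 6.64 ± 0.29 in WT.

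Across stages, 10 genes were called at S1, S2 and S3, each in the same direction. Those higher were Itga4 (0.83, 0.88 and 1.93), Tlr1 (0.99, 1.07 and 2.21), Nr1d1 (1.23, 1.57 and 1.45), Tnfrsf25, Klf6, Spice1 and Anxa6. Those lower were Atp8a2, Il4 (-0.64, -1.11 and -0.98) and Serinc3. Of these only Tlr1 kept its call in all fits without an array at S1. There Il4, Atp8a2, Tnfrsf25 and Serinc3 lost theirs in 6 of 6 fits, Itga4, Klf6 and Anxa6 in 5, Spice1 in 4 and Nr1d1 in 3. Itga4, Nr1d1, Il4 and Klf6 kept theirs in all 6 fits at S2 and at S3, but at S2 Spice1 lost its call in 6 fits, Serinc3 and Tnfrsf25 in 4, Anxa6 in 3 and Atp8a2 in 1. At S3 Anxa6 lost its call in 6 fits and Spice1 in 1. Of the genes higher at S2 and at S3, 42 were shared where independent lists would share 2.18, and of those lower 13 against 0.62. No array entered the group means of both comparisons, but both used the same variance for a gene, which can raise the overlap. The stages may also come from the same mice, and differences between those mice would then raise it too. Of the gene lists compared between genotypes, only the quiescence list at S1 kept its call with an estimated correlation, at adjusted p = 0.0496.

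When the 3 stages of a genotype and replicate number were averaged first, so that each genotype had 3 values, 283 genes differed, 192 higher and 91 lower in Mst1KO. The lowest p-values were those of Itga4 (1.21 ± 0.06), Matn2 (-1.15 ± 0.06), Atp8a2 (-1.46 ± 0.08), Tlr1 (1.42 ± 0.08), Ccl5 (-1.13 ± 0.07), Il4 (-0.91 ± 0.07), the focal adhesion gene Tns4 (0.90 ± 0.07) and S1pr1 (1.19 ± 0.10). Of 17 NKT17 genes 9 were higher, 13 when adjusted over the list alone (camera adjusted p = 2.12e-11, adjusted p = 0.655 with an estimated correlation). Of 17 quiescence genes 3 were higher, 6 when adjusted over the list alone (adjusted p = 6.64e-05, adjusted p = 0.672 with an estimated correlation). Of 18 NKT1 genes 2 were lower and 1 higher, 5 lower and 1 higher when adjusted over the list alone (adjusted p = 0.00184, adjusted p = 0.694 with an estimated correlation). Leaving out WT replicate 1, 2 or 3 gave 180, 153 and 155 genes, and Mst1KO replicate 1, 2 or 3 gave 89, 90 and 64. A variance trend with a robust fit gave 551, and a fit of all 18 arrays with a random block gave 739.

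**Figure D3:**
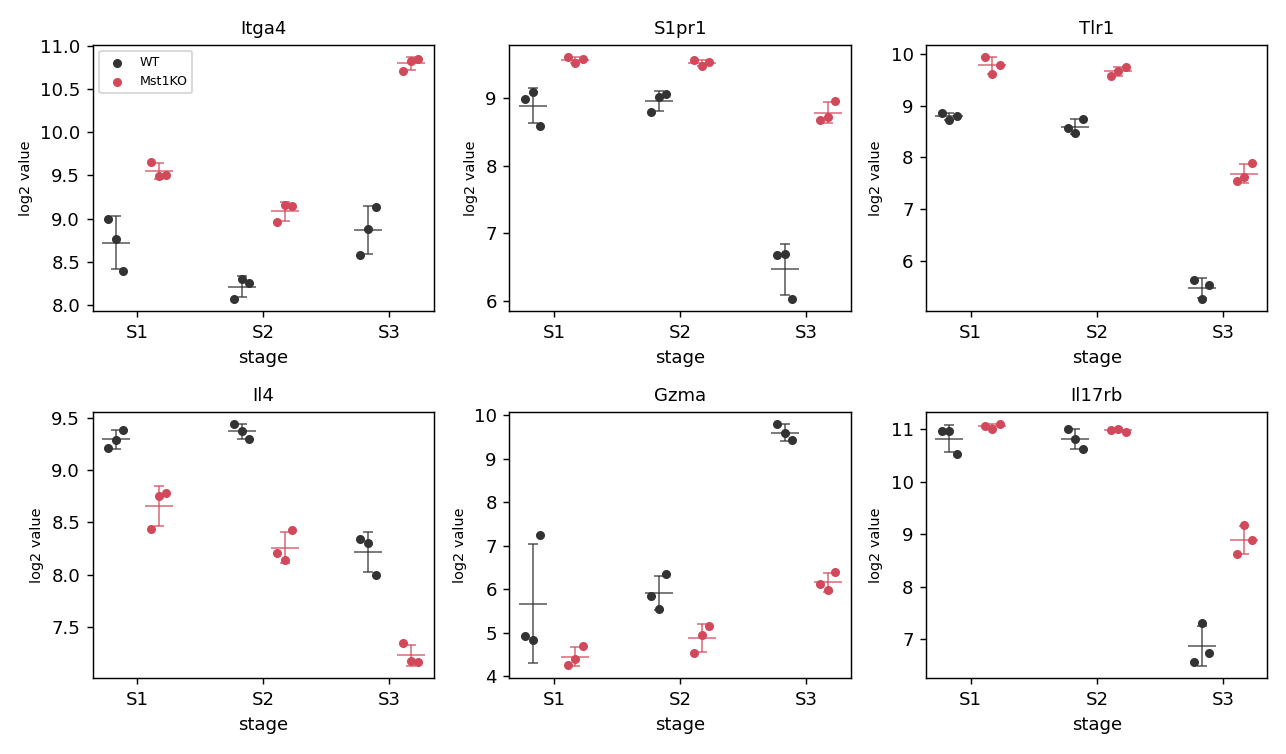
Log2 values of Itga4, S1pr1, Tlr1, Il4, Gzma and Il17rb on each array by stage, with points for arrays, bars for the group mean and SD (n = 3), WT in black and Mst1KO in red. Itga4 was higher and Il4 lower in Mst1KO at every stage, and at S3 S1pr1 stood at 8.79 ± 0.16 against 6.47 ± 0.38.

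Whether the knockout altered the change between stages was tested by the interaction. From S1 to S2 the change differed in 2 genes, with 882 at an unadjusted p under 0.05. Laptm4b rose by 1.37 in WT and by 3.74 in Mst1KO (difference 2.37 ± 0.30), and the Wnt pathway ubiquitin ligase Rnf43 was at -0.38 ± 0.13 in WT and rose by 1.31 in Mst1KO (difference 1.69 ± 0.18). From S2 to S3 the change differed in 48 genes, 34 positive and 14 negative, or 31 and 20 with quantile normalization repeated. S1pr1 fell by 2.49 on the log2 scale in WT and by 0.74 in Mst1KO (difference 1.75 ± 0.23), Il17rb fell by 3.95 and 2.10 (1.86 ± 0.25), and the transcription factor gene Myb fell by 2.75 and 0.88 (1.87 ± 0.22). Pdlim1 (1.49 ± 0.16), the integrin gene Itgb3 (1.36 ± 0.20) and 1700027F09Rik (1.80 ± 0.26) also had positive differences. Ifitm1 rose by 2.41 in WT and was at 0.13 ± 0.17 in Mst1KO (difference -2.28 ± 0.25), and Rubcnl differed by -1.54 ± 0.19. Leaving out WT S3 replicate 3 gave 93 genes and Mst1KO S3 replicate 3 gave 25. For S1 to S2 leaving out WT S2 replicate 2 gave 6, 3 positive and 3 negative, and leaving out Mst1KO S2 replicate 2 gave 4. A fit on only the S2 and S3 arrays called 15 genes.

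A maturation score, the mean of 1724 genes higher at S3 than S1 in WT minus the mean of 2044 genes lower, was compared between genotypes at S2. Only the S1 and S3 arrays of WT defined the genes. At S2 it was -0.26 ± 0.12 (SD, n = 3) in WT and -0.17 ± 0.04 (SD, n = 3) in Mst1KO, a difference of 0.09 with p = 0.4 in a two-sided exact permutation test, whose smallest possible p at 3 against 3 is 0.1, so it could not have shown a difference at 0.05. The difference was 0.159 without WT replicate 1 and 0.043 without WT replicate 2. Across the 13034 genes, the change from S1 to S3 in Mst1KO followed that in WT with a total least squares slope of 0.863 and r = 0.885, genes not being independent replicates. From S1 to S3, 4406 genes were called in WT and 3473 in Mst1KO. Of these 2727 were called in both in the same direction, where independent lists would share 246 higher and 345 lower. Both calls used the same variance for a gene, so the lists are not fully independent.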

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

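Tests of S2 cells within the S3 sort, of an NKT17-type subset and of conventional T cells in the S1 and S2 sorts were chosen only after the result was seen.

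The higher NKT17 genes in Mst1KO at S3 may come from S2 cells in the sort, from more NKT17-type cells, or from a change per cell. If S2 cells of average makeup were present, the 11 of 17 NKT17 genes with a log2 difference over 1 between Mst1KO S2 and WT S3 would imply a share of 28.6% (replicates 31.2, 29.2 and 25.4). Under the same cut 32 genes outside all lists, which fell by over 2 in WT and differed by under 0.3 between genotypes at S2, imply 15% (12.3, 14.5 and 18.3), and 401 of all 1705 genes outside the NKT17 list that fell imply 13.8, 17.3 and 20.8%. With a cut of 0.5 the ranges meet (34, 30.4 and 25.4 from 13 NKT17 genes against 18.5, 21.8 and 26.6 from 949). The ranges lie apart only at the cut of 1. The test was chosen after the NKT17 difference at S3 was seen, and the share is computed from that difference. A higher share therefore cannot decide, and average S2 cells are not excluded. Average S2 cells, a larger NKT17-type subset and a change per cell cannot be told apart in bulk RNA, where 14 of 17 members were positive.

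Cell cycle genes were also higher in Mst1KO at S3, and here S2 cells in the sort may account for the difference. The mitosis mean of WT replicate 3 (6.34) lay above that of Mst1KO replicate 1 (6.11). With the cut of 1 all 25 mitosis genes imply a share of S2 cells of 12.5% (5.73, 15.5 and 16.3) and 7 of 13 NKT2 genes 12% (8.79, 14.2 and 12.9), which overlap. Greater proliferation of S3 cells was not tested separately.

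Quiescence and egress genes were higher in Mst1KO at S1, which may reflect conventional mature T cells in the sort or a change within iNKT cells. The CD1d tetramer gate is meant to exclude conventional T cells, and how many passed it is not known. The 7 conventional T cell markers outside the list had a mean difference of 0.30 (SD 0.36, SE 0.13) at S1, but without Cd8b1, whose reading the CD8 bead step leaves uncertain, 0.22 (SE 0.13), under 2 SE. At S2 their mean was -0.038 (SD 0.28, SE 0.11) with 3 of 7 positive, while the list's mean was 0.25 with 15 of 17 positive. The markers as a set thus did not rise with the list at S2, although 1 SD above their mean just reached the list's mean. With 7 markers or fewer, the explanations cannot be told apart at either stage.

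The change from S1 to S2 differed between genotypes in 2 genes by limma, with 882 at an unadjusted p under 0.05, by 1.69 for Rnf43 and 2.37 for Laptm4b. In 100 groupings of the arrays, the real one included, genotypes were reassigned within each stage separately. As many genes were called in 8 of them, the real one included, with 4 in the highest other. A genotype difference present at both stages can then pass for an interaction. The regroupings therefore cannot decide, and chance is not excluded. The median differences of this change, each called by camera, were -0.35 for the NKT1 program, -0.20 for the NKT2 program, 0.88 for the NKT17 program and -0.22 for the interferon response. With an estimated correlation none of the 4 kept its call, with adjusted p = 0.605 for NKT1, NKT2 and interferon and adjusted p = 0.23 for NKT17, and fry called 0 lists.

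The change from S2 to S3 differed between genotypes in 48 genes, and 7 of 100 regroupings called as many, the real one included. The highest other count was 116. As for S1 to S2, a genotype difference at both stages can pass for an interaction in them. They therefore cannot decide, and chance is not excluded. Named genes were Ifitm1 at -2.28, Pdlim1 at 1.49, Myb at 1.87, Rubcnl at -1.54, S1pr1 at 1.75, Il17rb at 1.86, Itgb3 at 1.36 and 1700027F09Rik at 1.80. The median differences of lists called here were 0.53 for DNA replication, 0.87 for mitosis, 0.32 for the NKT1 program, 0.29 for the NKT2 program, 0.35 for the NKT17 program, 0.88 for histone genes and 0.39 for gamma-delta T cell markers. With an estimated correlation none of the 7 kept its call, with adjusted p = 0.311 at the lowest, and fry called 0.

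Among 8443 probe sets with no gene listed, which the comparisons leave out, 3 differed between genotypes at S1 and 8 at S3. Among 1021 probe sets with several gene symbols, 2 differed at S1, 5 at S2 and 13 at S3.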

How the results depend on the processing

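Only the refits without an array of the gene lists and of the genes called at all 3 stages were chosen after the result was seen. Of 297 calls of named genes 89 were lost in at least 1 fit without an array. Stk4 from S1 to S2 in WT, not called, turned from negative to 0.027 without WT S1 replicate 1 and was -0.17 without WT S1 replicate 3. The cause of the shifts below was not tested, except that fits with fewer arrays have fewer values. The number of arrays and the signal over background both limit how small a difference can be called.

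For Mst1KO against WT at S1 (43 genes) the count was 28 without a filter, 93 with the stricter filter, 128 with trend and robust fit, 93 with array weights, 5 with only the groups compared, and 9 to 23 without an array. At S2 (152) it was 248 with trend and robust fit, 97 with weights, 4 with only the groups compared, and 39 to 160 without an array. At S3 (443) it was 259 with the 1.5-fold threshold, 184 with only the groups compared, and 200 to 369 without an array. The average (283) gave 551 with trend and robust fit, 102 with the 1.5-fold threshold, 739 with a random block, and 64 to 180 without a replicate.

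For S2 against S1 in WT (501) the 1.5-fold threshold gave 320, only the groups compared 195, and fits without an array 295 to 494. For S3 against S2 in WT (3073) these were 1560, 2037 and 2515 to 2932. In Mst1KO the 1.5-fold threshold gave 545 and 1208, and fits without an array 530 to 704 and 1547 to 1859. The interaction from S1 to S2 gave 4 with number as a block and 2 to 6 without an array, and from S2 to S3 15 with only the groups compared and 25 to 93 without an array. Against 20 lists called between genotypes, 1 was called with an estimated correlation, 10 with fry and 17 to 23 without an array. Of those 20 themselves, 1 kept its call with an estimated correlation, 7 with fry and 11 in every fit without an array. The slope ranged from 0.836 to 0.890 and the score difference from 0.043 to 0.159. Deviations of the arrays from their group means were also correlated across genes. Pairs of stages of a genotype with the same replicate number lay at -0.05 to 0.21 (3 of 18 above 0.1). Pairs with different numbers lay at -0.18 to 0.07 (0 of 36). Pairs of genotypes at a stage with the same number lay at -0.05 to 0.08 (0 of 9), and the correlation within blocks was 0.037. Among the 3 numbers in the other stages of their genotype, 17 of 18 arrays correlated best with their own. This is a hint from the data, not the design, that arrays with the same number are linked.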

Other observations

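The test of clock genes was chosen only after the result was seen. Nr1d1, a repressor of the circadian clock, was higher in Mst1KO at each stage (1.23, 1.57 and 1.45), and a different time of day at collection could raise it. The 5 clock genes taken to run in phase with it had a mean difference of 0.15 (SD 0.14) at S1, with 5 of 5 positive. At S2 it was 0.06 (SD 0.27), with 2 of 5 positive. At S3 it was -0.32 (SD 0.12) with 0 of 5 positive, which argues against a shift that moves these genes together with Nr1d1. They need not peak at the same hour as Nr1d1, so other differences in collection time are not excluded. The 3 clock genes taken as the opposite phase should fall if they move strictly against Nr1d1. They were higher by a mean of 0.19 (SD 0.10) at S1, 0.43 (SD 0.13) at S2 and 0.85 (SD 0.50) at S3. All 3 were positive at each stage, and the SD is over genes. At S1 Arntl (0.15 ± 0.12), Npas2 (0.30 ± 0.18) and Cry1 (0.12 ± 0.14) each lay within 2 SE of 0, which leaves such a shift open. At S2 they were at 0.30 ± 0.12, 0.44 ± 0.18 and 0.55 ± 0.14, which argues against such a shift only. The stages may come from the same mice, so a time of day cannot be judged stage by stage and stays open. None passed by limma at S2 (adjusted p = 0.386, 0.373 and 0.108). The values of these clock genes came from the fit without a filter. Thra, which overlaps Nr1d1 on the opposite strand, differed by 0.61, 0.58 and 0.18.

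S1pr1 in Mst1KO at S3 would need a share of 54.6% S2 cells in the sort to reach its level. The other genes that fell from S2 to S3 imply 15%. S1pr1 was named because its increase at S3 was among the largest, and its share is computed from that same difference. How the share varies among single other genes was not examined. The higher share of S1pr1 therefore cannot decide whether S2 cells in the sort account for its level.

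Other groupings of the same arrays into 3 and 3 were counted for each comparison, and 10 splits are too few for a share under 0.05. The real and the highest other count were 43 and 0 for Mst1KO against WT at S1, 152 and 1 at S2, 443 and 7 at S3 and 283 and 1 for the average. For the stages they were 501 and 2 for S2 against S1 in WT, 3073 and 2 for S3 against S2 in WT, and 870 and 0 and 2240 and 0 in Mst1KO. In each case 1 split, the real one, called as many genes.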
